A study of Mus musculus with 108 samples.

How the data were processed

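The values are log2 fluorescence as deposited by the authors, from single-colour Cy3 Agilent arrays. How the images were read, how background was handled and how the values were normalized is not given in the sources used here. The values show that they were set within each group of 3 arrays, because the brightest tied probes average 16 over the 3 arrays of every group. They do not show any scaling between groups, so array scale and centring remain unknown. A probe that a group lacks is empty on all 3 of its arrays in nearly every case, with 99.891% of probes per group missing on all or none, and 51.4% of all values were empty.

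The tables hold 41189 entries, of which 93 are controls. Of the other 41096 probes, 32609 have 1 gene symbol, 44 have several and 8443 have none. Probes without a single symbol were left out of gene results, and 12898 probes had no value on any array. For the 6066 genes with several probes the brightest was used. Arrays were scaled by their 75th percentile over the 12210 probes measured on all arrays, because the medians of arrays spanned 1.04 log2 in the clofibrate arm (0.77 in the other), over the limit of 1 set before the data were examined. Those medians were taken over the values each array lists, and the probes listed differ by group. Over the probes measured on all arrays, medians in the clofibrate arm ran from 10.783 to 11.5. The statistical model, the fixed gene lists, the rule for naming genes and most alternatives were also chosen before the data were examined. A gene was tested where each group compared had its values, and a gene saturated in both groups was left out. Between 156 and 423 probes per group lay at the scanner limit near log2 16.

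Each arm was fitted in limma with 1 mean per group and a variance trend, and p values of limma were adjusted by Benjamini-Hochberg within a comparison at 0.05. The mean effect weighs the 9 times equally. The difference of the compounds was fitted on both arms together, and vehicle livers over time were tested with an F test over 2 to 24 h. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The 31 lists include 9 of cell markers. Named genes are members of the lists, the 10 highest and 10 lowest mean effects of each compound among genes called for the mean and at 3 or more times, the 3 highest and 3 lowest at each time whose treated arrays all lay beyond the vehicle arrays, and the 8 highest and 8 lowest mean differences. Intervals are 95% intervals, and those of slopes come from 1000 bootstrap resamples of genes.

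Whether replicate numbers pair treated and vehicle animals is not stated. The residuals of treated and vehicle arrays of equal number correlated above 0.1 for every number in 16 of 18 comparisons, the others being clofibrate at 8 h and 1 day. The unpaired fit was kept as planned and the fit with number as a paired block is printed beside it, such as 2736 genes instead of 1082 for clofibrate at 8 h.

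The fits were tested on simulated data built on the real pattern of empty values. Noise was drawn independently for each probe and array, without the variation that real arrays of equal number share. The numbers of found and falsely called genes may therefore not carry over to the real arrays. Of 100 genes raised or lowered 2-fold, 73 were found in the clofibrate comparison at 8 h, 72 in that of Wy14643 at 8 h, 32 in the difference at 24 h, 99 in the mean of Wy14643, 98 in the mean difference and 68 in the vehicle time course. At 1.5-fold these numbers were 28, 16, 9, 92, 88 and 27. With nothing changed 1 of 10160 genes was called. Averaging all listed probes of a gene gave 594 false calls of 10215 in the same data, because the probes listed change between groups. Each alternative setting is described with its results in the section on settings, and those added later were chosen after seeing the data: values without scaling, median scaling, the brightest probe that is never saturated, an average over the same probes on every array, leaving out a copied array, and the mean without the 1 day groups. Probes without a gene name and genes listed in only 1 of the groups compared were not analysed beyond their counts. The analysis used R 4.3.3, limma 3.58.1, the R package data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.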

Results

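The series measured liver RNA of ovariectomized female C57BL/6 mice on 108 single-colour Cy3 Agilent arrays. Mice received by gavage either clofibrate or Wy14643, each at 300 mg/kg, or sesame oil. Both compounds are ligands of PPAR alpha, the nuclear receptor that turns on fatty acid breakdown in liver. The arrays form 2 arms of 54. Each arm holds a treated and a vehicle group at 2, 4, 8, 12, 18 and 24 h after a first dose and at 1, 4 and 14 days of daily dosing, with 3 arrays per group. One vehicle array of the clofibrate arm at 14 days is nearly identical to one at 4 days (correlation 0.99998), so that group may hold only 2 arrays of its own. The groups at 24 h and 1 day both stand about a day after a single dose. Of the 41096 probes that are not controls, 15750 to 21658 carried a value on an array of the clofibrate arm and 19738 to 22227 on one of the Wy14643 arm. In all 15129 genes had a value on some array. Values given below are log2 differences from the time-matched vehicle of the same arm ± SE from limma, with 3 arrays per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The brightest probes reach the scanner limit near log2 16, and a fold of a gene whose treated arrays all lie there is a lower bound.

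Clofibrate against vehicle asked how a weaker PPAR alpha ligand changes the liver over time. The pyruvate dehydrogenase kinase Pdk4, which spares glucose when fat is burned, rose 27-fold (log2 4.76 ± 0.50) at 2 h, 72.1-fold (6.17 ± 0.50) at 4 h and 62.3-fold (5.96 ± 0.50) at 8 h. At 12 h its difference was 0.89 ± 0.50, which was not called. The mitochondrial thioesterase Acot2 rose by 4.78 ± 0.28 and the lipid droplet protein Cidec by 3.58 ± 0.24 at 8 h. The cytochrome P450 Cyp4a12b, which hydroxylates fatty acids at their far end, was still raised 5.21-fold (2.38 ± 0.41) at 24 h and 13.6-fold (3.77 ± 0.41) at 1 day. The earlier call was lost without any 1 of the treated replicates (Cyp4a12b, clofibrate 24h, limma, adjusted p = 0.0641 to 0.0834) and without vehicle replicate 2 (0.222), while the difference stayed at 2.33 to 2.46 and 2.2. The later one kept its call without vehicle replicate 3, which lay low, and stood at 3.16 there (Cyp4a12b, clofibrate 1d). At 14 days Cyp4a12b lay at 13.42 to 13.46 in treated arrays, beside vehicle arrays at 11.42 and 11.71 and the copied one at 13.5. Genes lower at 3 or more times were only Adamts7, the aryl hydrocarbon receptor Ahr and the tyrosylprotein sulfotransferase Tpst1, and Ahr was down by 4 h (-1.51 ± 0.21).

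Called genes went from 28 higher and 2 lower at 2 h to 160 and 129 at 4 h and 593 and 489 of 9509 tested at 8 h, then to 110 and 44 at 12 h and 19 and 0 at 18 h. At 24 h 5 genes were higher, namely Cyp4a12b, Ehhadh, Retsat, Vnn1 and Vwa8 (1.16 ± 0.24), the last of which was chosen after its values were seen. The count of 0 lower genes in limma at 18 and 24 h stood beside 367 and 88 genes of either direction at an unadjusted p under 0.05, and with the paired block 7 genes were lower at 18 h. At 1 day 16 genes were higher and 1 lower, at 4 days 22 and 10, and at 14 days Cyp4a12a, Krt23 and Mogat1 were higher and Sdr9c7 lower, and the count there was also 4 without the copied vehicle array, although Krt23 was then not called. Without treated replicate 1 the calls of Krt23 and Sdr9c7 were lost (limma, adjusted p = 0.169 and 0.0745). With replicate numbers as a paired block, the totals were 66, 986, 2736, 513, 59, 9, 39, 221 and 2 in the order of the times, against 30, 289, 1082, 154, 19, 5, 17, 32 and 4 without it. Leaving out treated replicate 3 gave totals of 18 at 2 h, 337 at 8 h and 6 at 1 day, and treated replicate 1 gave 0 at 24 h, 2 at 4 days and 2 at 14 days. Leaving out vehicle replicate 2 gave 85 at 12 h, 12 at 18 h and 318 for the mean, and vehicle replicate 1 gave 114 at 4 h. For the mean over the 9 times, 272 genes were higher and 210 lower of 8116, and 62 and 7 of them passed 1.5-fold. The share of higher genes for that mean was 56.4% and fell to 20.7% when arrays were scaled on all listed probes. At 8 h the share went from 54.8% to 4.52% under that scaling and to 18.4% in the values as deposited, while at 4 h it went from 55.4% to 21.3% and 89.3%. With the paired block lower genes were the more numerous at 4 h and for the mean.

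**Figure D1:**
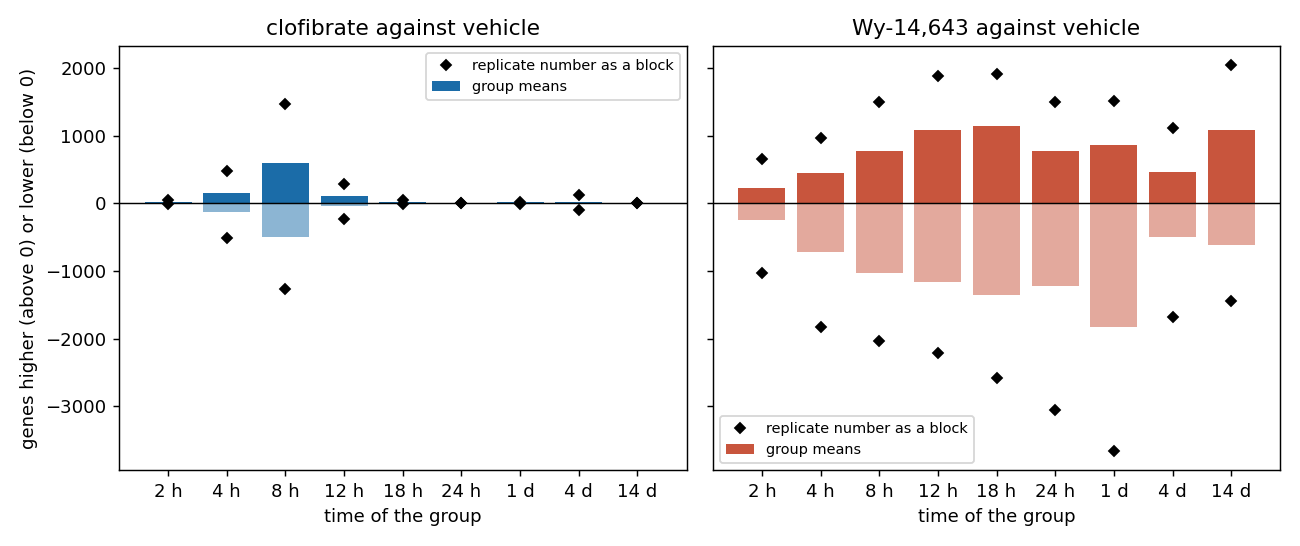
Bars give the number of genes called higher (above 0) or lower (below 0) than vehicle at each time for clofibrate (left) and Wy14643 (right), from 3 arrays per group, and diamonds give the same with replicate number as a block. The treated group of clofibrate at 8 h lists the fewest probes of all groups (15762 against 19724 in its vehicle), and 2170 genes had a value only in vehicle there. The clofibrate bars peak at 8 h and nearly vanish by 24 h, where 5 genes remain, whereas Wy14643 keeps at least 963 called genes from 4 h to 14 days.

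In the mean effect 10 of 14 tested genes of mitochondrial beta-oxidation rose and none fell (12 adjusted over the list alone), 10 of 16 of peroxisomal beta-oxidation rose (12) and 4 of 6 of omega-oxidation rose (5). The carnitine transporter Slc22a5 rose by 2.58 ± 0.24 at 12 h and the carnitine acetyltransferase Crat by 2.93 ± 0.32 at 4 h, and at 18 h both were no longer called, at 0.65 ± 0.24 and 0.35 ± 0.32. The muscle-type carnitine palmitoyltransferase Cpt1b was up from 2 h (1.35 ± 0.32) to 18 h (2.15 ± 0.32) and peaked at 8 h (2.94 ± 0.32). Of the trifunctional protein, Hadha reached 1.02 ± 0.26 and Hadhb 1.06 ± 0.24, and the dienoyl-CoA reductase Decr1 reached 1.72 ± 0.20. The bifunctional peroxisomal enzyme Ehhadh stayed up at every time from 2 h (1.98 ± 0.36) to 1 day (2.74 ± 0.36). Its treated arrays were saturated from 4 to 24 h, which makes those folds lower bounds. The 1 day value rests in part on vehicle replicate 3, at 11.33 beside 13.94 and 13.65. At 14 days Ehhadh lay at 15.77 to 16.05 in treated arrays and at 14.33 and 14.35 in 2 vehicle arrays. The third vehicle array, the copied one, lay at 15.77, so the lack of a call there does not show a fading of Ehhadh. The saturase Retsat, which acts on retinol, was up from 4 h (1.25 ± 0.31) to 1 day and stood at 2.87 ± 0.31 at 1 day. Members of the Cyp4a and Acot families resemble each other, so probes may take up signal of a sister gene. The camera calls for these 3 lists held with an estimated correlation (adjusted p = 1.09e-06, 7.33e-06 and 1.4e-07).

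In the list of lipid droplet and fatty acid uptake genes 10 of 15 rose (14 adjusted over the list alone), and among ketogenesis and fasting genes 3 of 6 rose (4), with estimated-correlation adjusted p of 1.57e-06 and 0.00192. The lipolysis inhibitor G0s2 rose by 3.22 ± 0.49 at 4 h, the hypoxia-inducible droplet protein Hilpda by 1.98 ± 0.25 and the droplet-forming Fitm2 by 1.72 ± 0.23 at 8 h. Perilipins Plin4 and Plin5 rose at 4 h (2.40 ± 0.50 and 1.18 ± 0.31) and 8 h (1.60 ± 0.50 and 1.60 ± 0.31), and the fatty acid transporter Cd36 from 8 h (2.24 ± 0.31) to 18 h (1.92 ± 0.31). Among immediate early genes Jun rose by 1.78 ± 0.28 at 4 h, and the growth arrest gene Gadd45b by 3.03 ± 0.49. Named falls at single times included the cytokine signalling suppressor Socs2 at 4 h (-2.27 ± 0.60), the G protein regulator Rgs16 at 8 h (-3.84 ± 0.65) and the insulin-like growth factor binding protein Igfbp1 at 8 h (-2.89 ± 0.72). The call of Socs2 was lost without treated replicate 1 (adjusted p = 0.144) and the call of Igfbp1 was lost without vehicle replicate 2 (0.0549). Averaging all listed probes turned the direction of Socs2, though that average also made false calls in simulated data.

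Interferon response genes were lower with clofibrate, 5 of 8 for the mean effect and all 8 adjusted over the list alone, and the camera call held with an estimated correlation (adjusted p = 0.0163). The ubiquitin-like protein Isg15 differed by -0.44 ± 0.11 and Mx2 by -0.45 ± 0.08 for the mean. Antigen presentation had 2 of 5 lower (4 adjusted over the list alone), the immunoproteasome subunits Psmb8 (-0.51 ± 0.09) and Psmb9 (-0.44 ± 0.11), and amino acid breakdown 2 of 10 (4), Hal (-0.28 ± 0.09) and Prodh (-0.26 ± 0.08). The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.154 and 0.194), as was that of the acute phase list (0.846), which was also lost with the paired block (0.116) and without treated replicate 1 (0.202). Of the latter limma called 0 of 18 genes for the mean, and 0 over the list alone, but 2 as lower with the paired block. At 4 days the metallothioneins Mt1 (2.67 ± 0.57) and Mt2 (at least 2.79) were higher and the chaperones Creld2 (-2.26 ± 0.45) and Hsph1 (-1.67 ± 0.32) lower. Without treated replicate 1 the calls of Mt2, Creld2 and Hsph1 were lost (adjusted p = 0.0868, 0.106 and 0.138). The other lists were not called for clofibrate. Their called members for the mean were Sqle (-0.36 ± 0.10) and Mvd (-0.54 ± 0.15) of 15 cholesterol genes, Abcc4 (0.46 ± 0.09) of 12 bile acid genes, Nnmt of 11 tryptophan genes, Ephx1 (0.57 ± 0.16) of 11 NRF2 targets (2 over the list alone), Nfil3 (-0.51 ± 0.14) of 9 clock genes, Pklr and Gpd2 of 8 glucose genes, Apoa4 and Mttp of 6 lipoprotein genes and Jun, Junb and Egr1 of 9 immediate early genes. For the mean over the 9 times, no gene was called in limma among fatty acid synthesis (13 tested), the cell cycle (16) and CAR and PXR targets (8). The same held for sex-biased genes (3), ER stress (8) and every cell marker list. Calls at single times are not counted here. With the paired block 1 gene was lower in each of the CAR and PXR, ER stress and lymphocyte lists, and the lymphocyte list had 1 lower adjusted over the list alone. For fatty acid synthesis, bile acids and glucose genes the sign of the median and that of the test differed.

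Wy14643 against vehicle asked the same of a ligand with a higher affinity for PPAR alpha. Pdk4 rose at least 128-fold (log2 7.00 ± 0.40, saturated) at 8 h and remained 6.9-fold (2.79 ± 0.40) higher at 14 days. Cidec rose 93.2-fold (6.54 ± 0.26) at 18 h, Acot2 by 6.25 ± 0.21 at 12 h and the surface protein Ly6d by 6.67 ± 0.46 at 18 h. The bile acid enzyme Cyp7a1, which starts the conversion of cholesterol to bile acids, fell 43.3-fold (-5.44 ± 0.66) at 4 h on its brightest probe, and by -2.62 log2 on the other. The methyltransferase Nnmt, which acts on nicotinamide, fell 10.1-fold (-3.33 ± 0.28) at 14 days.

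For the mean over the 9 times 2122 genes were higher and 3666 lower of 10273, with 379 and 513 past 1.5-fold. Single times gave 235 higher and 250 lower at 2 h, 448 and 711 at 4 h, 777 and 1030 at 8 h, 1082 and 1160 at 12 h, 1144 and 1359 at 18 h, 778 and 1225 at 24 h, 863 and 1833 at 1 day, 461 and 502 at 4 days and 1090 and 615 at 14 days. With the replicate numbers as a paired block the totals were 1692, 2799, 3538, 4104, 4508, 4565, 5184, 2800 and 3488. Of the genes called at 18 h, 2399 of 2503 had all treated arrays above or all below all vehicle arrays, as did 41.2% of all measured genes against 10% by chance. With clofibrate that share ran from 3.81% at 1 day to 25.3% at 8 h and was under 10% at 2 h, 24 h, 1 day and 14 days. The median of all genes lay at -0.14 at 24 h and -0.16 at 1 day. Whether more genes were higher or lower turned under at least 1 other scaling at every time but 14 days. At 4 h 1639 were higher and 208 lower in the values as deposited, and at 18 h the excess of lower genes grew to 646 and 3323 with scaling on all listed probes, which took the share of higher genes at 8 h from 43% to 61.5%. That share also moved from 38.8% to 53.2% at 24 h and from 32.0% to 53.3% at 1 day under quantile normalization, and to 92.3% and 97.1% in the values as deposited, and for the mean it went from 36.7% to 70% in the latter. Leaving out vehicle replicate 3 lowered the total at 1 day from 2696 to 1598, treated replicate 1 that at 2 h to 200, treated replicate 2 those at 4 h and 8 h to 737 and 1184, treated replicate 3 that at 4 days to 503 and vehicle replicate 2 that at 14 days to 1040. In all 36 genes were higher at every one of the 9 times, among them Acot8, Cidec, Clstn3, Cpt1b, Crat, Cyp4a12b, Ly6d, Pdk4, Pex11a, Slc16a1, Slc22a5, Slc25a20, Trpv2 and Vnn1. The nucleoside transporter Slc29a1, the chromatin remodeller Smarcd2 and 4930581F22Rik were lower at all 9 and were chosen after their values were seen.

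All 14 tested genes of mitochondrial beta-oxidation rose in the mean effect of Wy14643, 13 of 16 of peroxisomal beta-oxidation rose and 1 fell (14 and 1 adjusted over the list alone), and 5 of 6 ketogenesis genes rose and 1 fell. All 16 tested lipid droplet and uptake genes rose. Camera called these 4 lists with either correlation (adjusted p with the estimated one 1.5e-05, 0.00028, 0.00126 and 8.26e-09). Cpt1b went from 1.82 ± 0.26 at 2 h to 4.79 ± 0.26 at 14 days, Slc22a5 peaked at 3.98 ± 0.20 at 18 h and the carnitine carrier Slc25a20 at 2.11 ± 0.12 at 24 h. In peroxisomes the thioesterase Acot8 peaked at 18 h (2.26 ± 0.13), Crat stood at 3.04 ± 0.24 at 24 h and the division factor Pex11a was up at least 2.57 at 18 h. The monocarboxylate transporter Slc16a1 rose by 1.79 ± 0.20 at 12 h, and the hormone Fgf21, made by the fasting liver, by 3.05 ± 0.49 at 2 h and 2.75 ± 0.49 at 24 h. Cd36 rose by 4.14 ± 0.34 at 24 h, the lipoprotein lipase Lpl by 3.97 ± 0.34 at 14 days and the fatty acid binding protein Fabp4 by 2.42 ± 0.24 at 24 h. Late droplet genes were Cidea (6.81 ± 0.26 at 4 days) and Fabp3 (6.24 ± 0.32 at 4 days and at least 8.93 at 14 days). For omega-oxidation 4 of 6 rose and 2 fell, with Cyp4a31 at 4.62 ± 0.44 at 1 day (3.88 without vehicle replicate 3) and Cyp4f14 at -2.81 ± 0.30 at 14 days, and the call was lost with an estimated correlation (adjusted p = 0.521), with the paired block (0.103) and without treated replicate 2 (0.0613).

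**Figure D2:**
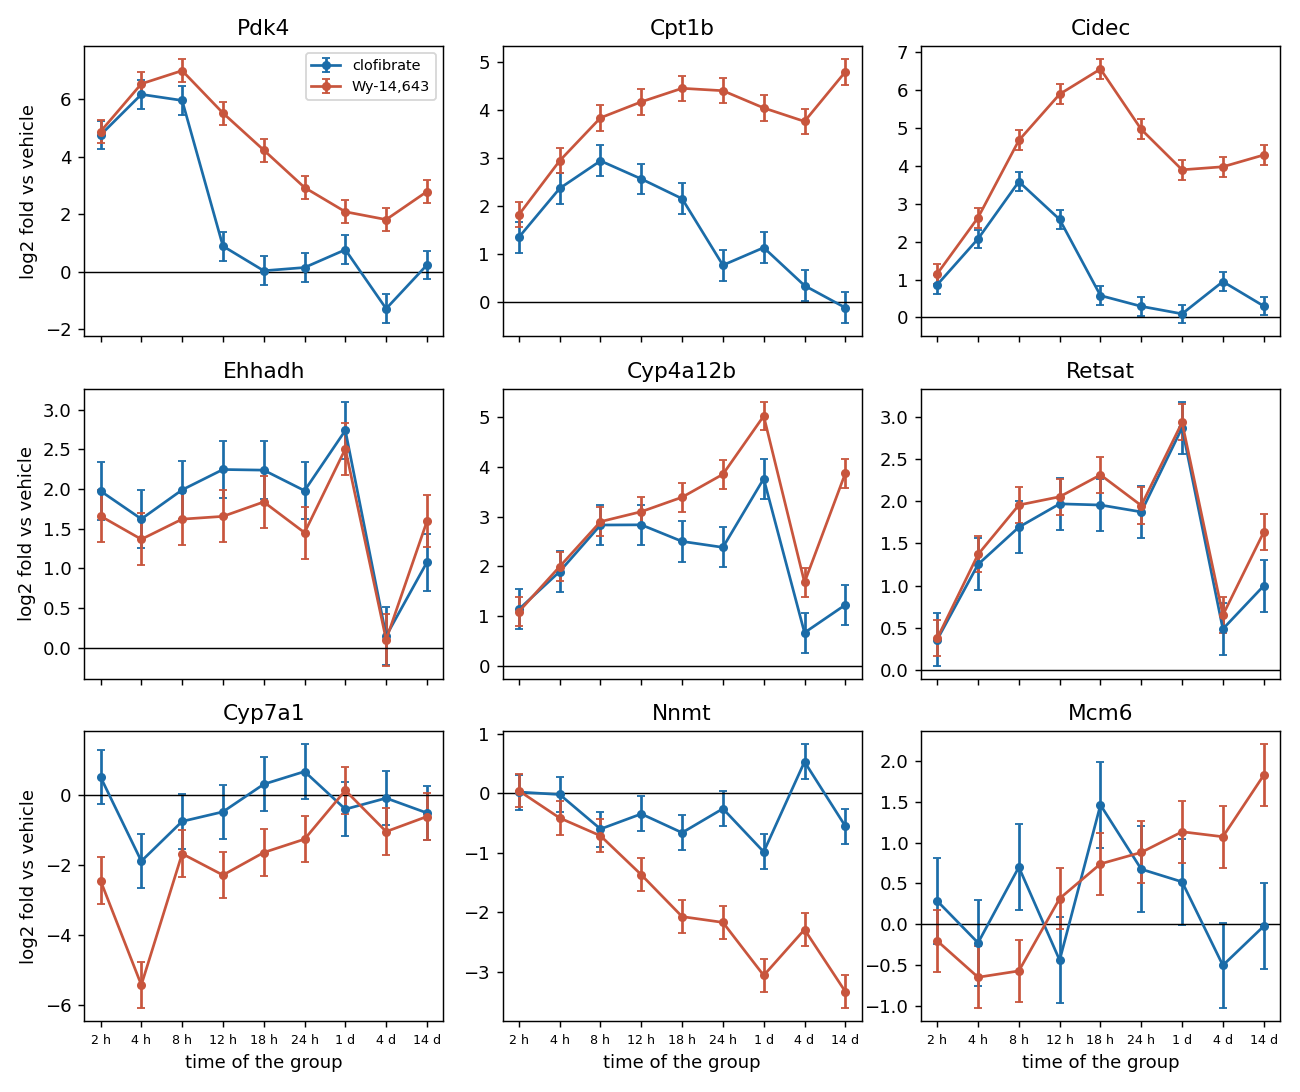
Points give the log2 difference from time-matched vehicle for clofibrate (blue) and Wy14643 (red) at the 9 times in 9 genes, with error bars of 1 SE from limma and 3 arrays per group. Pdk4, Cpt1b and Cidec return towards 0 with clofibrate between 8 and 24 h, Pdk4 by 12 h, but stay raised with Wy14643. Values of Wy14643 for Pdk4 at 2 to 8 h, for Ehhadh and for Retsat from 18 h are lower bounds. So are Nnmt at 8 to 18 h with either compound and Ehhadh with clofibrate except at 2 h and 1 day. At 4 days vehicle arrays of Ehhadh also lie at the limit, so neither of its points there can be read.

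In cholesterol synthesis 10 of 16 genes fell and 1 rose, with Lss at -1.25 ± 0.31 and Mvk at -1.42 ± 0.30 at 8 h, but the list was not called (adjusted p = 0.134). Among bile acid genes 7 of 13 fell and 3 rose (adjusted p = 0.816). The export pump Abcc4 rose by 3.16 ± 0.25 at 14 days while the conjugating enzyme Baat fell (-1.05 ± 0.18) at 18 h. Fatty acid synthesis was split, 6 up and 5 down of 13 (0.536), where the ATP citrate lyase Acly fell (-2.16 ± 0.40) and the malic enzyme Me1 rose (1.57 ± 0.41) at 12 h. Amino acid breakdown and the urea cycle fell in all 10 tested genes, and this call held with an estimated correlation (adjusted p = 0.0262). Histidine ammonia-lyase Hal reached -2.54 ± 0.24, the urea cycle enzyme Asl -1.94 ± 0.28 and proline dehydrogenase Prodh -2.48 ± 0.23. In the tryptophan list 6 of 11 fell and 1 rose (0.12), with Haao at -1.08 ± 0.17 at 24 h and the dioxygenase Tdo2, the 1 that rose, at 0.65 ± 0.07 for the mean, a lower bound as it was saturated at 8 h. CAR and PXR targets fell in 6 of 8 (0.12), as Cyp2c39 did (-1.23 ± 0.38) at 18 h. Among NRF2 targets 5 of 11 rose and 2 fell (0.12), led by the sulfiredoxin Srxn1 (2.12 ± 0.22 at 12 h) and the epoxide hydrolase Ephx1 (2.57 ± 0.43 at 1 day).

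Of the acute phase and complement list 15 of 19 fell and none rose, with complement C9 at -3.01 ± 0.26 and C8a at -2.29 ± 0.30 at 14 days and the fibrinogen chain Fga at -1.73 ± 0.35 at 18 h. The camera call (adjusted p = 0.000427) was lost with an estimated correlation (0.521). Interferon response genes fell in 8 of 8, with Oasl1 at -1.74 ± 0.19 and Ifit1 at -1.58 ± 0.30 at 24 h, and antigen presentation in 7 of 8 (8 adjusted over the list alone), and these calls were lost too (0.148 and 0.521). That of antigen presentation was lost also with the paired block (0.0543) and without treated replicate 1. Kupffer cell markers fell in 9 of 10 (adjusted p = 0.0833), with C1qb at -0.33 ± 0.07 for the mean. Cell cycle genes rose in 18 of 22 and fell in 1 (Tk1), with Mcm5 at 1.61 ± 0.48 at 18 h and Cdk1 at 1.81 ± 0.44, Aurka at 1.77 ± 0.56 and the helicase subunit Mcm6 at 1.82 ± 0.38 at 14 days, and this call was also lost with an estimated correlation (0.521). The sulfotransferase Sult3a1, which female livers express more than male ones, fell (-5.43 ± 0.65) at 14 days, and sex-biased genes fell in 3 of 4 (0.286).

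The remaining lists were not called for Wy14643. Clock genes fell in 8 of 11 and rose in 1, with Per2 at -2.16 ± 0.45 at 14 days, ER stress genes fell in 5 and rose in 2 of 10, immediate early genes fell in 5 and rose in 4 of 10, glucose genes fell in 3 and rose in 2 of 8, and lipoprotein genes fell in 3 and rose in 2 of 6. The liver pyruvate kinase Pklr fell (-2.18 ± 0.37) at 24 h, Junb (-2.70 ± 0.39) at 12 h and Apoa4 (-2.24 ± 0.28) at 14 days. Among cell markers 2 of 5 lymphocyte, 4 of 9 stellate (3 over the list alone), 2 of 8 endothelial (1), 2 of 3 cholangiocyte, 1 of 3 erythroid and 2 of 3 acinar genes fell, the single neutrophil gene tested did not pass, and adipocyte markers had no gene to test. Over all genes 3666 of 10273 were lower for the mean, so such counts alone say little about a list. Median, mean and test differed in sign for fatty acid synthesis, immediate early, lipoprotein and endothelial genes.

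Wy14643 minus clofibrate asked whether the compounds, at matched dose and time, differ in effect. For the mean over the 9 times Wy14643 raised Cidec more by 2.96 (95% interval 2.72 to 3.20), Cpt1b by 2.30 (95% interval 2.02 to 2.58), and Fgf21 by 2.18 (95% interval 1.68 to 2.69) on the log2 scale. For Pdk4, saturated with Wy14643 at 2 to 8 h, it was at least 2.24. It lowered Cyp7a1 further, by -1.51 (95% interval -2.21 to -0.82). For Nnmt no size is read, as vehicle arrays of both arms were saturated at 8 to 18 h. Retsat is saturated with Wy14643 from 18 h on, so its mean difference is not read. At 12 h it differed by 0.08 (95% interval -0.68 to 0.85), which was not called.

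At 2 h and 4 h limma called 0 genes (127 and 256 at an unadjusted p under 0.05, and 3 at 4 h with the paired block). At 8 h it called 3 genes, Enc1 (1.72 ± 0.33), Pmm1 (1.35 ± 0.28) and Rad9a (-1.12 ± 0.22), chosen after their values were seen. With the block 61 were called at 8 h. Cidec differed by 0.56 (95% interval -0.16 to 1.28) at 4 h and by 1.09 (95% interval 0.37 to 1.80) at 8 h and Cpt1b by 0.89 (95% interval 0.06 to 1.73) at 8 h, none of them called. Pdk4 was saturated with Wy14643 at these times, so its difference is not read. Intervals of this width leave room for differences of more than 1.5-fold. From 12 h the numbers were 51 higher and 29 lower, 174 and 132 at 18 h, 143 and 87 at 24 h, 51 and 37 at 1 day, 72 and 41 at 4 days, 133 and 65 at 14 days and 597 and 882 of 8045 for the mean, of which 139 and 155 passed 1.5-fold. With the block the totals from 12 h on were 402, 1052, 859, 471, 612 and 650, and 2925 for the mean. At 18 h Cidec differed by 5.96 (95% interval 5.25 to 6.68), Ly6d by 4.82 (95% interval 3.05 to 6.59) and Slc22a5 by 3.33 (95% interval 2.71 to 3.96), Pdk4 at 12 h by 4.64 (95% interval 3.32 to 5.95), and at 14 days Cpt1b by 4.90 (95% interval 4.06 to 5.74) and Sult3a1 by -5.77 (95% interval -7.88 to -3.66). The median of all genes was -0.10 at 24 h. For the mean the share of genes higher with Wy14643 was 40.4%, and 71.1% with scaling on all listed probes. That scaling gave 2060 higher and 1 lower at 8 h and 135 and 412 at 18 h, and took the share at 14 days from 67.2% to 45.7%. With the paired block lower genes were the more numerous at 8, 18 and 24 h, 1 day and 4 days. Leaving out treated replicate 3 lowered the total from 306 to 138 at 18 h, from 230 to 112 at 24 h and from 113 to 27 at 4 days, treated replicate 2 that at 12 h to 31, vehicle replicate 2 that at 1 day to 37 and vehicle replicate 1 that at 14 days to 98 and the copied vehicle array that at 14 days to 131, and the total at 8 h ranged from 0 without vehicle replicate 1 to 77 without treated replicate 1. In 100 redrawn groupings of the arrays the counts at 8 h and 1 day were reached by 12 and 27, so chance is not excluded there in the unpaired fit. Those at 12 h, 18 h, 4 days and 14 days were reached by 4, 2, 3 and 4, without correction for the number of times. Chance is not firmly excluded at these times either. The redraws ignore the pairing by number, and the blocked counts of 61 at 8 h and 471 at 1 day were not redrawn.

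By list, the difference for the mean was higher with Wy14643 in 9 of 13 mitochondrial (10 adjusted over the list alone), 9 of 13 peroxisomal (10), 5 of 6 ketogenesis and 13 of 14 lipid droplet genes, and in none of these was it lower. It was lower in 8 of 10 amino acid genes (10 over the list alone), with Hal at -1.09 (95% interval -1.34 to -0.85), and in 4 of 10 tryptophan genes. These 6 calls held with an estimated correlation (adjusted p = 4.8e-05, 4.78e-05, 4.78e-05, 2.12e-08, 0.00125 and 0.0135). Calls for omega-oxidation (3 of 5 higher, 1 lower over the list alone), acute phase (6 of 18 lower), cell cycle (2 higher and 1 lower of 16, Mcm7, Pcna and Tk1, against 7 and 1 over the list alone), CAR and PXR targets (3 of 8 lower, 4 over the list alone) and interferon genes (6 of 8 lower) were lost with it (0.3, 0.459, 0.508, 0.459 and 0.341). With the paired block those of omega-oxidation and of CAR and PXR targets were lost as well (both 0.114). The omega-oxidation call was lost also without treated replicate 2 (adjusted p = 0.0933) and that of CAR and PXR targets without treated replicate 1 (0.196). Crat differed by 1.56 (95% interval 1.29 to 1.82), Slc22a5 by 1.64 (95% interval 1.43 to 1.85), Cd36 by 1.41 (95% interval 1.10 to 1.72), Hilpda by 1.38 (95% interval 1.13 to 1.64) and Abcc4 by 1.52 (95% interval 1.27 to 1.78). Hadh (0.17 (95% interval -0.06 to 0.39)) and Etfa (0.04 (95% interval -0.14 to 0.21)) were not called, and for Ehhadh saturation left no test.

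Calls overlapped between the compounds. Of 271 genes higher with clofibrate for the mean and tested in both arms, 269 were also higher with Wy14643 (60.6 if the calls were independent), and of 207 lower genes 206 were (71.4), with none opposite. At 4 days only 7 of 21 higher and 3 of 10 lower genes were shared, 1 was opposite and effects correlated at 0.218. The other 3 for the mean, Anapc4, Nat8 and Slc5a6, were chosen after their values were seen. The correlation of mean effects across genes was 0.859 (covariance 0.0508), against 0.143 (0.00104) in simulated data without any compound effect whose vehicle arrays varied together as observed. Part of it may come from shared controls, and genes are not independent replicates. At 1 day the observed 0.603 stood beside a simulated 0.474. Both compounds called 658 genes at 8 h, all but 1 in the same direction. In these the clofibrate effects were 0.873 (95% interval 0.853 to 0.896) of those of Wy14643 at 8 h. The slope was 0.472 (0.438 to 0.505) at 12 h, 0.14 (0.11 to 0.174) at 24 h and 0.287 (0.237 to 0.34) at 1 day. These genes were chosen partly by their clofibrate effect at 8 h. In genes chosen by Wy14643 alone, at 8 h and 24 h, the slopes were 0.737 (0.712 to 0.76) at 8 h, 0.142 (0.121 to 0.165) at 24 h and 0.278 (0.24 to 0.321) at 1 day.

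**Figure D3:**
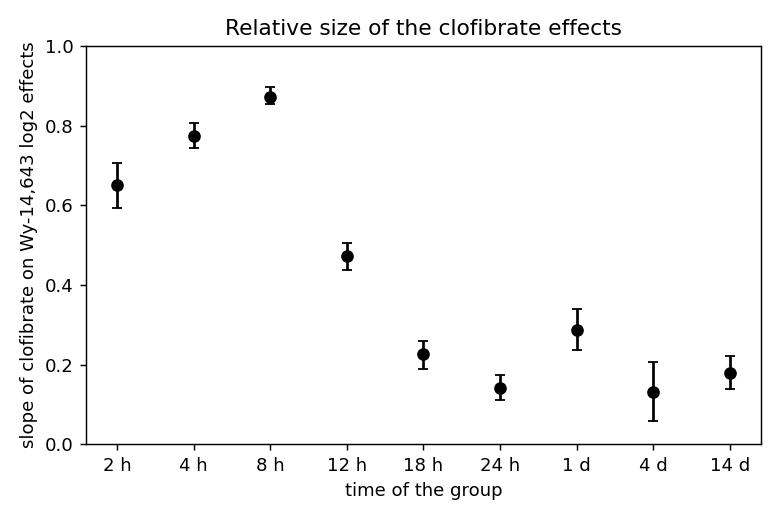
Points give the slope of clofibrate log2 effects on Wy14643 log2 effects across the genes called for both compounds at 8 h, all but 1 in the same direction. Bars give the 95% bootstrap interval over genes. The slope is 0.873 at 8 h, where the genes were selected, and 0.14 to 0.287 from 18 h to 1 day. At 4 and 14 days (0.13 and 0.18) vehicle livers with raised PPAR alpha targets and the copied array can lower clofibrate effects, so these slopes are not read as fading.

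The 24 h and 1 day groups repeat an interval in separate animals. For clofibrate limma called 0 genes between them (35 at an unadjusted p under 0.05), and for Wy14643 1 gene, the glycerophosphodiesterase Gpcpd1 (2.05 ± 0.32, adjusted p = 0.0016, chosen after its values were seen), with 547 unadjusted and 51 with the paired block. Without treated replicate 1 that count was 0, and without vehicle replicate 1 it was 4. Vehicle livers changed over the first day in 1029 of 9633 genes in the clofibrate arm and 2860 of 10778 in the Wy14643 arm, and without vehicle replicate 2 in 237 and 1234. Clock genes were called in 6 of 9 and 8 of 10. Between the arms, vehicle arrays differed in 4572 of 9266 genes for the mean, 1927 higher and 2645 lower in the Wy14643 arm, and the share higher went from 42.1% to 89.9% with scaling on all listed probes. Without vehicle replicate 2 that total was 2631. Arm is not separable from anything else that differed between the arms, such as the run of the arrays. The fit treats vehicle arrays of the arms as separate animals, although they may come from the same livers.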

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

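Of the tests in this part, those on treated arrays that might be vehicle, on shared vehicle animals, on Lcn2 alone and on chance list by list were chosen after the result was seen, and the others before it. Arrays were also redrawn at random between groups. For a single comparison the 10 possible splits of 3 against 3 are too few to exclude chance, and in all but clofibrate at 1 day only 1 of the 10, the real one, reached the count. The real and highest other counts for clofibrate were 30 and 1 at 2 h, 289 and 134 at 4 h, 1082 and 278 at 8 h, 154 and 0 at 12 h, 19 and 0 at 18 h, 5 and 0 at 24 h, 32 and 16 at 4 days and 4 and 3 at 14 days. At 1 day they were 17 and 513, with 5 of 10 splits at 17 or more, which points to structure among those 6 arrays other than treatment. Treated replicate 2 and vehicle replicate 3 there had high Lcn2 (15.26 and 15.97, the others 6.745 to 9.759). For Wy14643 they were 485 and 15, 1159 and 4, 1807 and 19, 2242 and 0, 2503 and 2, 2003 and 0, 2696 and 151, 963 and 1, and 1705 and 1 from 2 h to 14 days.

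With all times redrawn together in 100 groupings, chance was excluded for the mean effect of clofibrate (482 genes, highest other 31, reached by 1 of 100), the mean effect of Wy14643 (5788, 1073, by 1) and the mean difference (1479, 1, by 1). For the difference at single times, only the real grouping reached the count at 24 h (230 genes, highest other 1, by 1). That is the lowest share that 100 groupings can give, and it was not corrected for the number of times either. Few groupings reached the count at 12 h (80, 956, by 4), 18 h (306, 370, by 2), 4 days (113, 214, by 3) and 14 days (198, 400, by 4). These shares were not corrected for the number of times tested, and some redrawn groupings called more genes than the real one. Chance is therefore not firmly excluded at those times. Nor was chance excluded at 8 h (3, 690, by 12) and 1 day (88, 1296, by 27). At 2 h and 4 h the count in limma was 0 (127 and 256 genes at an unadjusted p under 0.05), which all 100 groupings reach by construction (highest other 11 and 1034), so the redraws say nothing there. The redraws use the unpaired fit and ignore the pairing by number, and the blocked counts of 61 at 8 h and 471 at 1 day were not redrawn. Highest other counts several times the real one, such as 956 at 12 h, point to sample structure. Chance was excluded for vehicle livers over time (1029, 212, by 1, and 2860, 593, by 1) and for vehicle arm against arm (4572, 579, by 1), but not for 24 h minus 1 day with Wy14643 (1, 171, by 49). With clofibrate the count was 0 in limma (35 at an unadjusted p under 0.05), which all 100 groupings reach (highest other 8), so nothing follows. The values were set, and probes left empty, within each group of 3 arrays. Redraws that break up these groups therefore cannot tell an effect of time, arm or treatment from processing by group.

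The number of lists called was not above chance: 9 for clofibrate (highest other 12, reached by 11 of 100), 10 for Wy14643 (15, by 17) and 11 for the difference (14, by 9). List by list, the p values of the peroxisomal, mitochondrial, ketogenesis and lipid droplet lists were reached by 1 of 100 in every comparison, the real one. Those of the acute phase list were reached by 41, 35 and 27 and those of the cell cycle list by 56, 27 and 24 for clofibrate, Wy14643 and the difference. Chance was also not excluded for the called lists of antigen presentation (31) and interferon genes (8) with Wy14643, amino acid breakdown with clofibrate (11), and interferon genes (22), CAR and PXR targets (24) and omega-oxidation (5) in the difference.

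The difference of the compounds was largest in Cidec (2.96), Ly6d (2.77), Cpt1b (2.30), Fgf21 (2.18), the keratin Krt23 (1.97), the channel Trpv2 (1.78) and Clstn3 (1.77). It was lowest in Sult3a1 (-1.70), the uridine phosphorylase Upp2 (-1.68), Fam47e (-1.65), Cyp7a1 (-1.51), the integrin Itgb3 (-1.51), Dcaf12l2 (-1.41) and Lrtm1 (-1.38). Pdk4 (at least 2.24, being saturated with Wy14643 at 2 to 8 h) has no rank, and for Nnmt the fitted -1.39 is not read as a size, as vehicle arrays were saturated at 8 to 18 h. The other probe of Itgb3 hardly moved with Wy14643, at -0.0771 for the mean beside -2.08 and at 0.221 beside -3.38 at 12 h, so its fall rests on 1 probe. Probes without a gene name were also called for the mean effect, 48 of 1117 for clofibrate and 900 of 1836 for Wy14643.

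The clofibrate response was weaker at 12 h than at 8 h and weaker still at 24 h, and 3 technical explanations were tested. Lower precision of the clofibrate arm would hide effects but not shrink them, and the slope on Wy14643 effects was itself down to 0.14 at 24 h (0.287 at 1 day), so precision is excluded as the sole cause. Scaling by 1 constant per array moves all effects of a comparison alike, so it cannot change the slope except through the genes chosen. Most of the 5 scalings were therefore no test. Quantile normalization could change the slope, and there the ratio of the 24 h to the 8 h slope was 0.166 (at most 0.182 over the 5 scalings). That argues against scaling as the cause of the lower slope, but says nothing on the counts of called genes. Whether treated arrays were in fact vehicle stays open. All 3 of Ehhadh, Cyp4a12b and Retsat were higher at 24 h or 1 day with treated arrays above all vehicle arrays. But these were the 3 highest genes at 24 h under a rule that asked for that separation. The outcome was thus fixed by the choice of genes, and the arrays at 18 h were not covered. The fading may reflect faster clearance of clofibrate, which a measurement of its active acid in the same livers could test.

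Vehicle arrays of the arms with the same time and number varied together. For the clock, acute phase, immediate early and cell cycle lists, the pairing by number was the best of all pairings at 9 of 9 times, against 1.5 by chance, with a mean correlation of 0.778. Over all genes it was the best at 7 of 9 times, with a mean correlation of 0.286. This is consistent with the same animals having been hybridised for both arms. A batch that follows the replicate number through all times is argued against, as arrays of the same number at other times had a median correlation of 0.0385. The same-time medians over all genes ran from 0.0493 at 8 h to 0.681 at 1 day. Treated arrays of the arms hardly varied together (mean correlation -0.0334 over all genes and 0.0964 over the lists), unlike what a batch common to treated and vehicle arrays predicts. A batch of vehicle arrays alone within 1 time was not tested. If vehicle animals are shared, the difference of the compounds has a smaller error than limma assumed, and the correlation of their effects is partly built in.

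The many genes lower with Wy14643 at 1 day might rest on vehicle replicate 3, which had high Lcn2. Without it the lower genes went from 1833 to 1113 and the higher ones from 863 to 542. Calls were thus lost in both directions, and the explanation stays open. For Lcn2, Mt1 and Mt2 together it is excluded, since their median effect kept 0.842 of its size, while for Lcn2 alone 0.436 was kept (from -4.00 to -1.74, adjusted p = 0.293 in limma), which stays open.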

How the results depend on the processing

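Across all settings, 1599 of 1670 list results kept their status as called or not called, 47 lost and 24 gained a call, and no called one reversed. Lists called in neither setting, which are most of them, counted as kept whatever their direction. Of 2618 results for named genes 2500 stayed, 117 lost their call and 1 reversed. Counts of genes moved far more. The cause was not tested unless a sentence below gives it. Signal over background was not judged, as only listed values are known, so a gene that drops under the detection limit in 1 group has no fold and weak changes near that limit are missed.

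Quantile normalization raised the count of clofibrate at 1 day from 17 to 30 (27 higher, 3 lower) and that of the difference at 8 h from 3 to 10, all higher with Wy14643. The other 36 counts stayed within 1.5 times. It moved the share of higher genes from 38.7% to 51.2% for Wy14643 at 4 h and from 47.9% to 59.8% at 4 days, and for clofibrate from 100% to 84.6% at 18 h and from 68.8% to 54.8% at 4 days. Median scaling moved that share to 42.3% for Wy14643 at 1 day, to 60.5% at 4 days and to 68.2% for the difference at 1 day (58% in the main result), and moved no count by more than 1.5 times.

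Scaling on the 75th percentile of all listed probes gave clofibrate 539 genes at 4 h (115 higher, 424 lower), 3698 at 8 h (167, 3531) and 927 for the mean (192, 735), and Wy14643 3969 at 18 h (646, 3323). The difference gave 2061 at 8 h (2060, 1), 547 at 18 h (135, 412) and 196 at 1 day (179, 17). Vehicle livers over time in the clofibrate arm gave 4875. This percentile is taken over different probes in each group, since the probes listed differ by group. It moved the share of higher genes of Wy14643 to 52.4% at 4 h, 61.5% at 8 h (43% in the main result), 16.3% at 18 h (45.7%), 54.6% at 24 h, 50.9% at 1 day and 58.7% at 4 days, and that of clofibrate to 60% at 1 day (94.1%) and 57.1% at 4 days. For the difference it gave 24.7% at 18 h (56.9%), 91.3% at 1 day, 80.3% at 4 days (63.7%) and 45.7% at 14 days (67.2%).

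Without any scaling, clofibrate at 1 day had 80 genes (79 higher, 1 lower). Wy14643 had 1847 at 4 h (1639, 208), 3649 at 24 h (3367, 282) and 6626 at 1 day (6436, 190), and its 24 h minus 1 day comparison had 6 (1, 5). The difference had 5 at 8 h (4, 1), 577 at 18 h (127, 450), 538 at 24 h (509, 29) and 267 at 1 day (251, 16). Vehicle livers over time gave 1798 in the clofibrate arm and 5324 in the other. The share of higher genes was 88.7% for Wy14643 at 4 h, 31.5% at 18 h and 64.3% at 4 days, 85% for the clofibrate mean, and for the difference 22% at 18 h, 94.6% at 24 h (62.2% in the main result), 94% at 1 day, 79.5% at 4 days, 50.3% at 14 days and 68.5% for the mean. For vehicle arm against arm it was 25.8%.

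Averaging all listed probes of a gene raised clofibrate to 559 genes at 2 h, 977 at 4 h, 2462 at 8 h, 805 at 12 h, 564 at 18 h, 628 at 24 h, 524 at 1 day, 589 at 4 days, 509 at 14 days and 1577 for the mean. It raised Wy14643 to 1217 at 2 h, 1981 at 4 h and 1789 at 4 days. The 24 h minus 1 day comparisons gave 647 for clofibrate and 749 for Wy14643. The difference gave 756, 786, 1398, 910, 1282, 1258, 1097, 1035 and 1107 from 2 h to 14 days and 2753 for the mean, and vehicle livers over time 3083 in the clofibrate arm and 4397 in the other. Lists called for the difference went from 11 to 6, and Socs2 with clofibrate at 4 h went from -2.27 to 0.54. In simulated data with nothing changed this average made 594 false calls of 10215 genes and the brightest probe 1 of 10160, because probes drop out by group. An average over the same probes on every array, chosen after this was seen, moved none of 38 counts by more than 1.5 times.

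A fit of all 36 groups gave clofibrate 453 genes at 4 h, 1662 at 8 h, 262 at 12 h, 32 at 18 h, 31 at 1 day and 69 at 4 days, all more than in the arm alone. Wy14643 had fewer, 303 at 2 h and 567 at 4 days, and 0 instead of 1 for 24 h minus 1 day in limma (547 at an unadjusted p under 0.05 in the arm alone). Vehicle livers over time in the clofibrate arm gave 1908. In this fit both arms share a variance, which is larger in the clofibrate arm. A fit of only the groups compared mostly lowered the counts, as fewer arrays estimate the variance. Clofibrate had 52 at 4 h, 238 at 8 h, 69 at 12 h, 2 at 24 h, 0 at 1 day, 6 at 4 days and 0 at 14 days. Wy14643 had 42 at 2 h, 423 at 4 h and 678 at 1 day. The difference had 0 at 8 h (539 at an unadjusted p under 0.05 in the fit of both arms), 398 at 24 h and 8 at 1 day.

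With the replicate number as a paired block within arm and time, clofibrate had 66, 986, 2736, 513, 59, 9, 39, 221 and 2 genes from 2 h to 14 days and 1295 for the mean. Wy14643 had 1692, 2799, 3538, 4104, 4508, 4565, 5184, 2800 and 3488, and 51 for 24 h minus 1 day. The difference had 3 at 4 h, 61 at 8 h, 402 at 12 h, 1052 at 18 h, 859 at 24 h, 471 at 1 day, 612 at 4 days, 650 at 14 days and 2925 for the mean. A block over all times gave 26 for clofibrate at 1 day and 183 for the difference at 4 days. With an estimated correlation between genes the lists called fell from 10 to 5 for Wy14643 (4 up, 1 down) and from 11 to 6 for the difference (4 up, 2 down). Leaving out the copied array, labelled as vehicle of the clofibrate arm at 14 days, lowered the difference at 14 days from 198 to 131. The brightest probe that is never saturated moved no count by more than 1.5 times.

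Leaving out 1 replicate number at a time gave the following lowest and highest counts. For clofibrate they were 18 (treated 3) to 23 (vehicle 1) at 2 h, 114 (vehicle 1) to 332 (treated 3) at 4 h, 337 (treated 3) to 1759 (treated 1) at 8 h, 85 (vehicle 2) to 118 (treated 1) at 12 h, 12 (vehicle 2) to 15 (vehicle 1) at 18 h, 0 (treated 1) to 5 (vehicle 3) at 24 h, 6 (treated 3) to 26 (vehicle 1) at 1 day, 2 (treated 1) to 79 (treated 2) at 4 days, 2 (treated 1) to 4 (vehicle 1) at 14 days and 318 (vehicle 2) to 460 (vehicle 1) for the mean. At 24 h clofibrate had 88 genes at an unadjusted p under 0.05 in limma with all arrays. For Wy14643 they were 200 (treated 1) to 628 (treated 3) at 2 h, 737 (treated 2) to 1054 (treated 1) at 4 h, 1184 (treated 2) to 1663 (vehicle 3) at 8 h, 1598 (vehicle 3) to 2690 (vehicle 2) at 1 day, 503 (treated 3) to 814 (vehicle 3) at 4 days, 1040 (vehicle 2) to 1664 (vehicle 3) at 14 days and, for 24 h minus 1 day, 0 (treated 1) to 4 (vehicle 1).

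For the difference they were 0 (vehicle 1) to 77 (treated 1) at 8 h, 31 (treated 2) to 90 (treated 3) at 12 h, 138 (treated 3) to 278 (treated 1) at 18 h, 112 (treated 3) to 159 (treated 1) at 24 h, 37 (vehicle 2) to 109 (treated 1) at 1 day, 27 (treated 3) to 107 (treated 2) at 4 days and 98 (vehicle 1) to 214 (vehicle 3) at 14 days. With all arrays 539 genes at 8 h had an unadjusted p under 0.05 in limma. Vehicle livers over time ranged from 237 (vehicle 2) to 1243 (treated 1) in the clofibrate arm and from 1234 (vehicle 2) to 2994 (treated 1) in the other, and vehicle arm against arm from 2631 (vehicle 2) to 4746 (treated 1). Treated arrays enter the vehicle results only through the variance.

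Calls of named genes that needed every array were mostly of clofibrate. Krt23 at 14 days lost its call without vehicle replicate 3 (adjusted p = 0.613), Sdr9c7 likewise (0.666), Cyp4a12b at 24 h without vehicle replicate 2 (0.222) and Ahr at 2 h without treated replicate 1 (0.122). With Wy14643, Cyp7a1 at 2 h lost its call without treated replicate 1 (0.273) and Derl3 at 18 h without vehicle replicate 2 (0.057).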

Other observations

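Vehicle livers changed with the hour after dosing, clock genes included. In the clofibrate arm and the Wy14643 arm the nuclear receptor Nr1d2, part of the clock, was highest at 8 h and lowest at 18 h with ranges of 3.45 and 3.67 log2, and Per2 was highest at 12 h and lowest at 24 h with 3.02 and 3.28. Cyp7a1 ranged over 4.85 and 4.66, highest at 8 h, and Pdk4 over 2.63 and 2.5, lowest at 8 h. Nampt, which makes NAD, ranged over 1.67 and 1.64. The 8 h rise of Pdk4 over vehicle thus starts from its lowest vehicle level. Interferon response genes changed over time in 6 of 9 and 8 of 9, lipid droplet genes in 5 of 16 and 10 of 16. As the arms may hold the same vehicle animals, these are not independent time courses.

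Vehicle livers at 4 days, a contrast chosen after the data were seen, differed from the other vehicle groups in some of the genes that PPAR alpha ligands raise. Vnn1 was higher by 1.42 in the clofibrate arm and 1.43 in the other, Cd36 by 1.12 and 1.09 and Ehhadh, next to the scanner limit at 4 days, by at least 1.98 and 1.64. In the clofibrate arm the other groups hold a copy of a 4 day array, and without it the values were 1.49, 1.14 and at least 2.04. Others were not called, such as Cidec (-0.0382 and -0.0816), Plin4 (-0.599 and -0.731) and Pdk4 (0.488 and 0.569), and the call of lipid droplet genes was lost with an estimated correlation (camera in limma, adjusted p = 0.306 and 0.0753). Mitochondrial beta-oxidation was called in both arms with an estimated correlation (camera in limma, adjusted p = 0.0122 and 0.0172, and 0.00491 for the former without the copy). The arms may hold the same vehicle animals, so their likeness here is not an independent repeat. Cell cycle genes were higher in 12 of 22 in the Wy14643 arm, among them Birc5 (2.35), and in none of 16 in the clofibrate arm (Birc5 2.14, adjusted p = 0.0862) or 4 without the copy. The list calls were lost with an estimated correlation (0.0753, 0.187 and 0.112). Treated arrays of Ehhadh lay at that limit too, so no effect of the compounds can be read for it at 4 days.

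Of the tests in this part, that on fasting was chosen before its result was seen and that on the copied array after. The 4 day vehicle animals may have been fasted. The test asked for lower fatty acid synthesis genes in both arms, and the higher adjusted p of the arms was 0.415 in limma, which leaves fasting open, since a p over the threshold excludes nothing. Records of feeding, or blood ketones of those animals, would decide.

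A vehicle array of the clofibrate arm stands under both 4 days and 14 days, with a correlation of 0.99998 between the entries against 0.99422 for the next highest pair. The 14 day label is likely the wrong one, as the array lay closer to the 4 day than to the 14 day vehicle array of the other arm by 0.0172 in correlation. Leaving it out left clofibrate effects at 14 days resting on 2 vehicle arrays.

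Clofibrate may act both less strongly and for a shorter time. At 8 h the slope was 0.873 in genes chosen by both compounds and 0.737 in genes chosen by Wy14643, each choice favouring the compounds it used, and at 2 h it was 0.651 in the former. At 24 h it was 0.14 and 0.142, but at 1 day, the same interval in other animals, 0.287 and 0.278. Vehicle arrays that vary together between the arms can raise the latter. In simulated data without any compound effect they gave a correlation of effects of 0.474 at 1 day and 0.0962 at 24 h. The higher slope at 1 day is therefore not read as a larger clofibrate effect. A second dose of clofibrate at 12 h, with livers taken at 24 h, would restore Cidec and Pdk4 if clearance sets the time course, and would not if the receptor response is spent.

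The histidine enzyme Hal was lower with both compounds at 8 h (-1.27 ± 0.27 with clofibrate and -1.38 ± 0.24 with Wy14643). For the amino acid list the redrawn groupings reached the p value in 1 of 100 with Wy14643 but in 11 of 100 with clofibrate, whose call was also lost with an estimated correlation (camera in limma, adjusted p = 0.194), so a direction shared by the list stays open. Livers lacking PPAR alpha would test whether the fall with Wy14643 needs the receptor.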
